A study of Mus musculus with 4 samples.

How the data were processed

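DNA copy number was measured by array comparative genomic hybridisation in 4 colorectal tumours of FVB mice, an inbred laboratory strain. Per the labels' protocols, p53 was deleted by 5 daily oral doses of 1 mg tamoxifen, the drug that switches on an inducible Cre recombinase. The mice then received azoxymethane, a colon carcinogen, by intraperitoneal injection at 10 mg/kg once a week for 6 weeks. The series title places the deletion in enterocytes, the absorptive cells of the gut lining. Tumour DNA carried the red dye Cy5. Liver DNA of healthy littermates carried the green dye Cy3 on the same array, per the labels. A ratio above 0 on a log scale therefore means more tumour than control signal. Dyes were not swapped on any of the 4 arrays. The tumours form 1 group with n = 4 and are numbered here in accession order, which is only a name. The labels treat them as separate tumours, but whether all come from separate animals is not given in the sources used here.

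The arrays were Agilent mouse arrays of 180880 spots, 4 to a slide, with probe positions on genome build mm9 (NCBI37) per the file headers. The scanner images were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Per the file headers, that software subtracted background with spatial detrending and scaled the dyes to each other by a linear factor. The deposited log10 ratio of red over green is the result. The authors' series value table held the same log10 ratio for every spot, with a largest difference of 0, so its scale and direction are known. Its columns had medians of 0.0067, 0, 0.0040 and 0.0054 for tumours 1 to 4 before centring. All 4 arrays were on 1 slide and scanned on 1 date, so no slide or scan batch could be tested.

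The log10 ratios were turned into log2 ratios. The 6575 control spots and between 98 and 124 spots per array with an outlier flag were left out. Repeat spots of a probe were averaged, which left 170305 probes: 161460 on autosomes, 8723 on chromosome X and 122 on chromosome Y. Each array was centred on the median of its autosomal probes, with no loess or quantile step. Neighbouring autosomal probes lay a median of 10843 bases apart and spanned 2407.8 Mb. Both channels were well above background at 99.4%, 93.3%, 98.1% and 99.1% of spots in tumours 1 to 4. The software's own measure of probe-to-probe noise was outside its accepted range on all 4 arrays, at 0.461, 0.377, 0.313 and 0.411 (log2). For arrays, the number of tumours and of probes in a region limits the precision.

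Each tumour was divided into segments of constant mean by least-squares optimal partitioning, chromosome by chromosome. The penalty per change point was 4 times ln(n) times the noise variance, where n is the number of autosomal probes and the noise comes from neighbouring probes. A segment needed at least 5 probes, and a gain or loss was called where the segment mean lay at least 0.2 from 0 on the log2 scale. Standard errors of segment means cover probe noise only. False calls were counted in 20 shuffles of the probe order per tumour, which gave 0 calls and 0 change points. Shuffling removes any correlation between neighbouring probes, so it covers independent probe noise and not false calls from a regional wave of the signal. Recurrence, the length called the same way in at least 2 tumours, was set against 1000 random circular shifts of each tumour along the joined autosomes. Medians of 1 Mb windows with at least 10 probes were tested against 0 over the 4 tumours with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Whole-chromosome medians were compared with an exact two-sided sign-flip test. That test cannot give a p below 0.125 with 4 tumours. Every ratio test leaves out the spread of the control DNA, and p-values of the window and sign-flip tests measure only the spread between these 4 samples. The p of the circular shifts measures no such spread: it sets the places of the calls against random places. Those shifts do not keep calls at chromosome ends, nor a wave that arrays share.

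Both procedures were tested on simulated data with the spread of values of these arrays. The simulations held no regional wave and no probe effects shared between arrays, so their rates do not cover those. Inserted segments of 500 probes at 0.3 and of 1500 probes at -0.3 were recovered in 100% of 19 cases in each tumour. Segments of 7 probes at -2.0 were recovered in 94.7% of cases in tumour 1 and in 100% in the other tumours. Segments of 100 probes at 0.4 were recovered in 0% of cases in tumours 1 and 4, 47.4% in tumour 2 and 100% in tumour 3, so short gains can be seen in tumour 3 that would be missed in the noisier arrays. The window test recovered 30% of 50 windows shifted by 0.1, 74% at 0.2 and 96% at 0.4, and called 13 of 2183 unshifted windows. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9.

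Before the data were examined, the alternatives fixed were normexp background correction with an offset of 50, the series value table, centring on the mode, a filter on dim or saturated spots, and loess on signal strength. Further ones were other penalties, minimum lengths and call thresholds, 5 Mb windows, window or chromosome means, each probe minus its median over the tumours, and leaving out each tumour in turn. The normexp fit used median signals of all spots, because the deposited files used here carry median and not mean raw intensity. After the data were seen, another pair of alternatives was added: each probe minus the median of the other 3 tumours, and loess on the number of probes within 500 kb.

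The rule for names fixed beforehand covered Trp53, 7 colorectal cancer genes, members of 13 gene lists inside called regions, the genes changed most across tumours, and the 5 calls of each tumour farthest from 0. Some of the 7 genes are not reported here. The array files used here give probe positions and no gene column, and the gene table used here is of assembly GRCm38.p6, not mm9. Positions were not converted between builds. For this reason 4 planned results were not analysed here: the Trp53 locus, genes changed across tumours, gene lists and antigen receptor loci. The gene table served only to say which chromosome a listed gene is on (324 of 328 list entries matched), and genes are named only where a whole chromosome was called or as lying on a chromosome. A correction for GC content was not run for the same reason, and loess on mean signal took its place as planned.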

Results

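The question was which parts of the genome had changed in copy number in colorectal tumours that arose after loss of p53 and exposure to azoxymethane, a colon carcinogen. p53, encoded by Trp53 on chromosome 11, is the tumour suppressor that halts or kills cells with damaged DNA. The data were 4 arrays, each setting DNA of 1 tumour against liver DNA of healthy littermates. Values are log2 ratios of tumour over control signal at 170305 probes, centred so that the autosomal median of each array is 0. A single extra copy of a chromosome in every cell would give 0.585 and the loss of 1 of a pair of copies -1.0, with smaller values where a share of the cells lacks the change. Noise between neighbouring probes was 0.47, 0.38, 0.32 and 0.42 in tumours 1 to 4. No tumour was measured more than once, so values for a single tumour carry only the error over its probes.

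The calls differed from tumour to tumour, and so did their extent. Tumour 4 had 218.7 Mb called as gained or lost, 9.08% of the autosomal span, mainly through loss of chromosome 14 and a series of losses and gains along chromosome 2. Tumour 1 had 50.5 Mb (2.10%) in a pair of large gains on chromosomes 2 and 11. Tumour 3 had 27.9 Mb (1.16%) in 14 short calls, 11 of them gains, and tumour 2 had 7.85 Mb (0.326%) in 3 calls. Together these were 27 calls, 18 gains and 9 losses. Whether the gains of tumour 3 and its losses on chromosomes 1 and 6 are changes of that tumour is not settled, as given below. The order by length depends on the call threshold. At 0.1, tumour 3 had 375.9 Mb and tumour 2 had 69.1 Mb, against 218.7 Mb in tumour 4 and 50.5 Mb in tumour 1. Normexp background correction gave 20 gains and 6 losses, loess on probe density 12 and 10, and subtracting each probe's median over the tumours 44 and 42. Under 7 other ways of computing the ratios, 9 of the 27 calls were found each time, of which 5 belong to tumour 4, 2 to tumour 2 and 1 each to tumours 1 and 3.

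**Figure D1:**
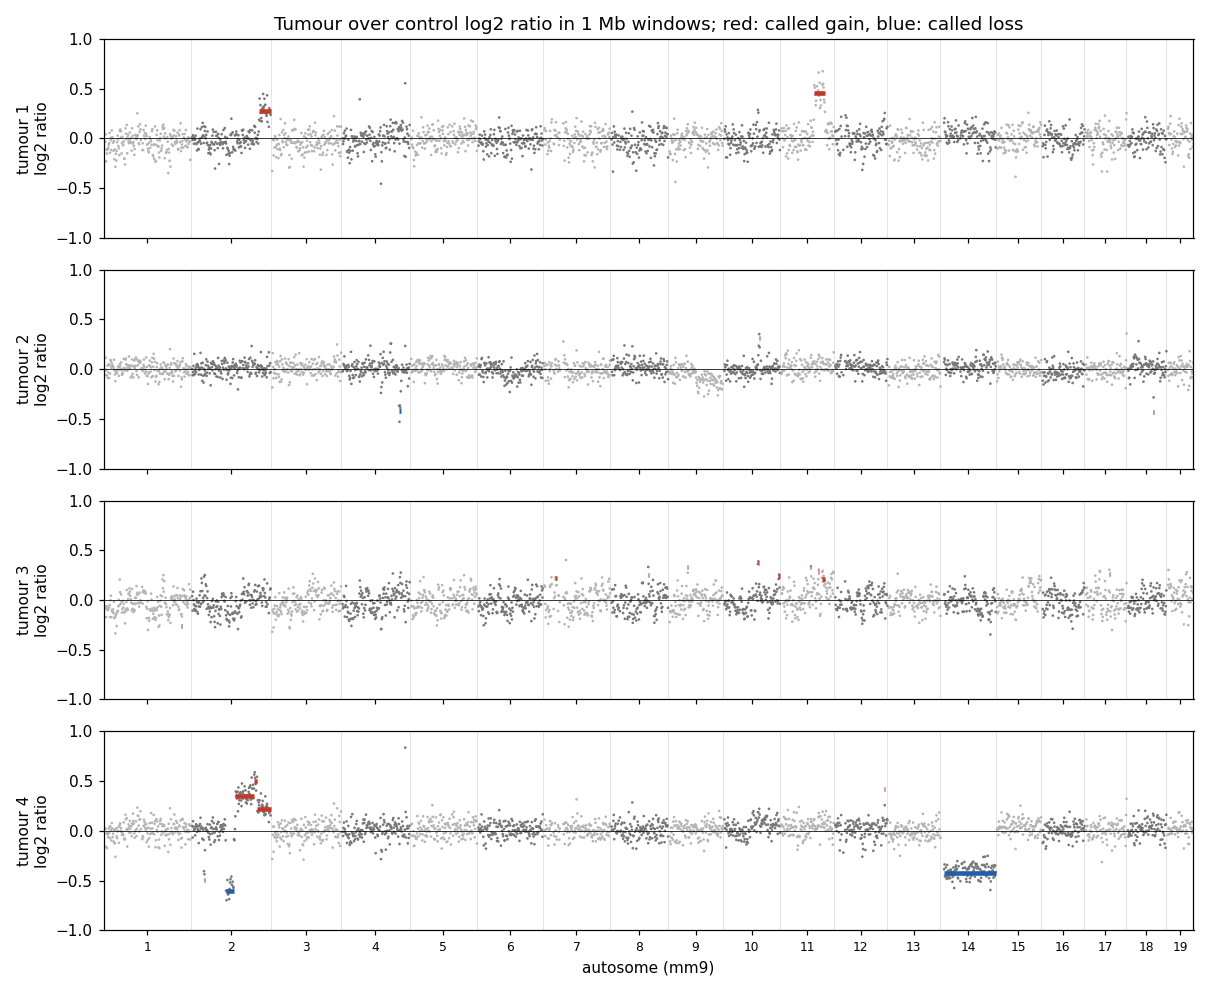
Log2 ratio of tumour over control along the autosomes (mm9), with a panel per tumour and a point per 1 Mb window median. Red and blue bars are called gains and losses. Loss of chromosome 14 and changes of chromosome 2 stand out in tumour 4, and gains on chromosomes 2 and 11 in tumour 1. The short losses on chromosome 6 lie below the axis range and are not drawn.

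Chromosome 14 was lost along its whole probed length in tumour 4. From 8526343 to 125164256, 7867 probes had a mean log2 ratio of -0.42 (SE 0.0048 over probes). The chromosome median in tumour 4 was -0.41, against 0.04, 0.02 and -0.01 in tumours 1 to 3. It was the only autosome whose median lay 0.2 or more from 0 in any tumour. The call was found under all 7 other ways of computing the ratios, with means between -0.36 and -0.47.

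Among the genes listed beforehand, 10 are on chromosome 14. The tumour suppressors are Rb1, which restrains entry into the cell cycle, and Bmpr1a, a receptor for bone morphogenetic proteins that is mutated in juvenile polyposis. Klf5 (a factor active in proliferating crypt cells, listed both as a colorectal oncogene and among intestinal genes), Olfm4 (a marker of intestinal stem cells) and Gata4 (a gut transcription factor) are on it too. The others are Fhit at a common fragile site, the DNA repair endonuclease gene Apex1, the signalling ligand gene Wnt5a, and the matrix-degrading enzymes Mmp14 and Plau. These genes come from 7 of the 13 lists. They have no separate measurement here, and their place on the chromosome follows a gene table of assembly GRCm38.p6.

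Chromosome 2 changed in steps in tumour 4. The stretch from 79788295 to 98049612 was lost (18.3 Mb, 1268 probes, mean -0.61, SE 0.012). A shorter loss lay from 30055742 to 32461158 (225 probes, mean -0.50, SE 0.028). Beyond 101717192 the rest of the chromosome was divided into 3 gained segments. The mean was 0.35 (SE 0.0076) up to 143633329, 0.50 (SE 0.019) from 143643187 to 151038158, and 0.22 (SE 0.0091) from 151198292 to the last probe at 181722086. The first 2 gains and both losses were called under all 7 other ways of computing the ratios, and the last gain under 4 of them. With a penalty of 8 ln(n) the first 2 gains were joined into 1 segment with a mean of 0.37, and the last stayed at 0.22. The fixed lists hold 24 genes on chromosome 2, which were not placed in these segments.

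Tumour 1 had gains on chromosomes 11 and 2 and no called loss. On chromosome 11, 2037 probes from 76634516 to 100726285 (24.1 Mb) had a mean of 0.46 (SE 0.011). On chromosome 2, 1788 probes from 155345841 to the last probe (26.4 Mb) had a mean of 0.27 (SE 0.011). The chromosome 11 gain was called under all 7 other ways of computing the ratios. The chromosome 2 gain was called under 6 of the 7 and not at a call threshold of 0.3. It was lost when each probe's median over the tumours was subtracted, which brought its mean to 0.15 and which takes away part of a change that tumours share. Chromosome 11 carries 29 of the listed genes, Trp53 among them, and whether Trp53 lies in the gain was not analysed here.

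**Figure D2:**
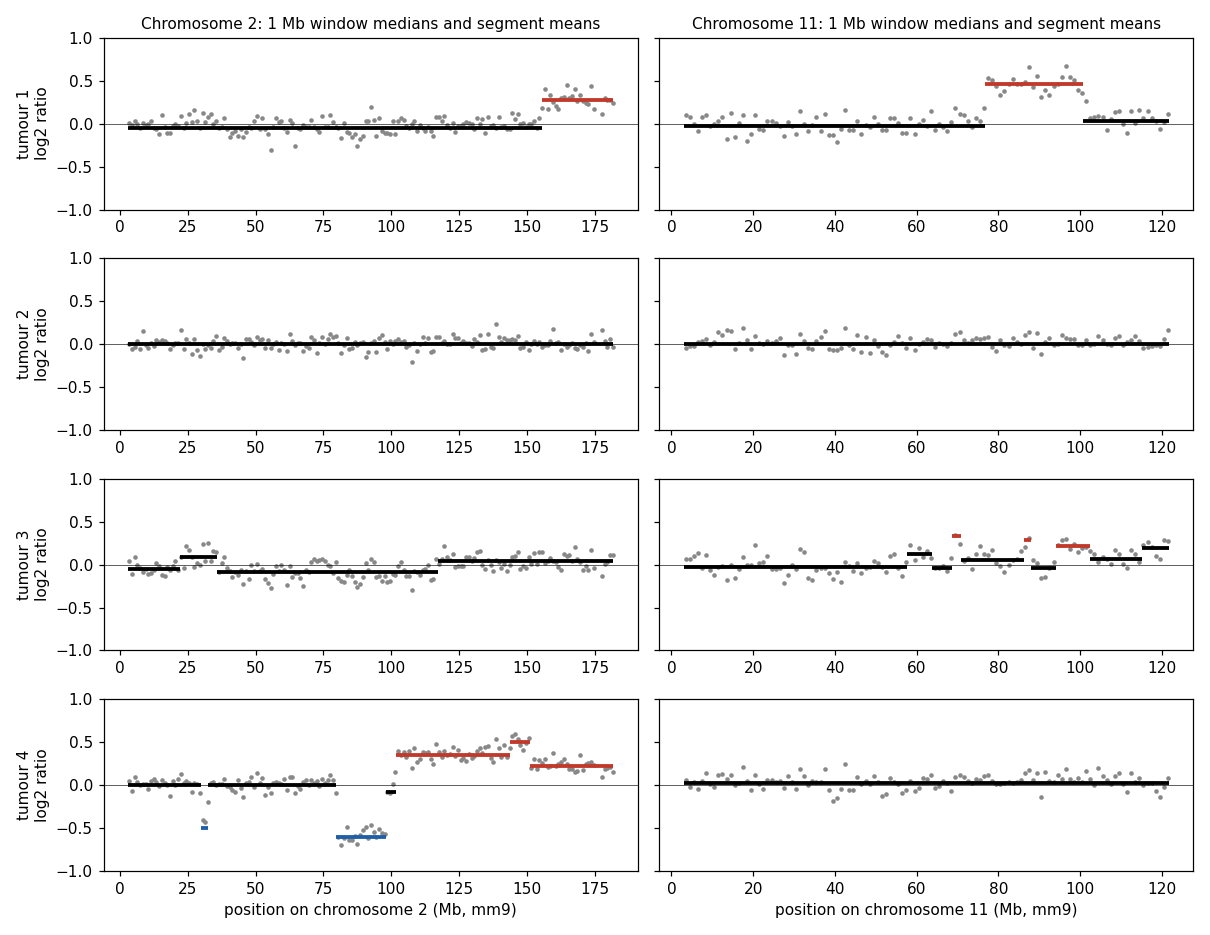
Log2 ratio of tumour over control along chromosomes 2 and 11 (position in Mb, mm9) in the 4 tumours. Grey points are medians of 1 Mb windows, and lines are means of segments of at least 20 probes, red for gains, blue for losses and black otherwise. Tumours 1 and 4 were both gained at the end of chromosome 2, at 0.27 and 0.22, where tumours 2 and 3 lay at -0.02 and 0.03.

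Tumour 2 had small losses on chromosomes 4 and 18 and a gain on chromosome 10. The loss on chromosome 4 ran from 130710250 to 135572557 (4.86 Mb, 431 probes, mean -0.42, SE 0.019). The loss on chromosome 18 covered 60925998 to 61740328 (77 probes, mean -0.43, SE 0.044). In the other 3 tumours the means of both regions were above 0, from 0.01 to 0.13. Both losses were called under all 7 other ways of computing the ratios, but with a penalty of 8 ln(n) the loss on chromosome 4 was the only call in this tumour. The gain on chromosome 10, from 81068959 to 83241425 (142 probes), had a mean of 0.31 (SE 0.032), and the same region was above 0 in the other 3 tumours, at 0.05, 0.14 and 0.16. Subtracting each probe's median over the tumours brought the gain to 0.16 and ended the call.

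Tumour 3 differed in having many short gains. Of its 11 gains, 10 were shorter than 4 Mb. The highest were on chromosome 13 from 23473987 to 23956139 (54 probes, mean 0.45, SE 0.043), on chromosome 7 from 51827644 to 53127308 (133 probes, mean 0.39, SE 0.028) and on chromosome 10 from 79016379 to 80986185 (205 probes, mean 0.37, SE 0.022). The remaining 8 had means of 0.22 to 0.33 and lay on chromosomes 7, 8, 9, 10, 11 and 17. All 11 lay in regions of high probe density, at percentiles 87.3 to 99.6 of random regions of the same probe number. In each the mean of the other 3 tumours was above 0 as well, although on chromosome 8 that mean was 0.0043. Of the 11, 2 overlap the chromosome 11 gain of tumour 1, and there tumours 2 and 4 were above 0 too. After a loess correction for local probe density, the means of the 11 gains were 0.16 to 0.38, with 8 of 11 at or above 0.2 and 4 still called. After subtraction of the median of the other tumours, 9 were still called. Both alternatives were added after the data were seen. The array of tumour 3 had the lowest noise of the 4, and its count of calls ranged from 3 to 42 over the penalties and thresholds tried. A loss on chromosome 1 from 175359048 to 177508634 had a mean of -0.26 (SE 0.024), and this region was below 0 in the other 3 tumours too, at -0.15, -0.17 and -0.23. That loss was called under 2 of the 7 other ways of computing the ratios, and subtracting the median of the other tumours brought it to -0.05.

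A very short region of chromosome 6 gave the lowest ratios outside the sex chromosomes. In tumour 4, 7 probes from 41036581 to 41101563 had a mean of -1.98 (SE 0.16). In tumour 3 the calls covered 41018389 to 41055972 (mean -1.16, SE 0.14) and 41066997 to 41112757 (mean -2.66, SE 0.14), with 5 probes each. Tumours 1 and 2 had means of 0.07 and 0.06 over the region called in tumour 4. Of the 7 spots there, 6 in the control channel and 1 in the tumour channel were well above background in each of tumours 3 and 4, so these ratios rest on a dim tumour channel. With normexp background correction their means lay between -0.38 and -0.27, and none of the 3 was called. None was called either with only spots well above background, which takes out dim spots on which the ratios rest. The mean in tumour 4 was then -0.06, and that of the first region in tumour 3 was -0.72, with no value left for the second. In tumour 4 a further short gain lay on chromosome 12 from 114817826 to 116291089 (113 probes, mean 0.42, SE 0.040). The median of its probes was lower, at 0.29. This gain was called under 4 of the 7 other ways of computing the ratios and not with a penalty of 8 ln(n).

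Few regions were called the same way in more than 1 tumour. Tumours 1 and 4 shared the gain of chromosome 2 from 155345841 to 181722086. Tumours 1 and 3 shared called gains on chromosome 11 from 86285515 to 87880824 and from 94016761 to 100726285. Tumours 2 and 4 had no call there but were above 0, at 0.12 and 0.18 in the first region and 0.03 and 0.07 in the second. Tumours 3 and 4 shared a called loss on chromosome 6 from 41036581 to 41101563. There the tumour channel of tumours 3 and 4 (-4.48 and -4.86 log2 from its autosomal median) lay near both channels of tumours 1 and 2 (-4.63 to -3.78). Only the control channel of tumours 3 and 4 was brighter, at -1.71 and -2.24, so a loss in the tumours is not shown. The shared length was 34.8 Mb, and 0 Mb was shared by 3 or more tumours. Of 1000 random circular shifts of the tumours, a share of 0.014 gave as much length (permutation p = 0.014), and their median was 1.38 Mb. The calls of tumour 3 in the shared gains of chromosome 11 were found under 4 and 1 of the 7 other ways of computing the ratios. The length fell to 1.69 Mb (permutation p = 0.38) with centring on the mode, when the gain of tumour 4 on chromosome 2 (0.18) and that of tumour 3 on chromosome 11 from 94016761 to 102310350 (0.19) both lay under the threshold. It was 0.08 Mb (permutation p = 0.46) without tumour 1 and 8.32 Mb (permutation p = 0.021) without tumour 4. A call threshold of 0.1 gave 34.78 Mb (permutation p = 0.46) and one of 0.3 gave 0.08 Mb (permutation p = 0.38). Subtracting each probe's median over the tumours gave 0.24 Mb (permutation p = 0.67), and subtracting the other tumours 1.02 Mb (permutation p = 0.91). The permutation p stayed under 0.05 with normexp, the filter on dim spots, both loess steps, and the other penalties and minimum lengths.

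No part of the autosomes passed a test over all 4 tumours. Of 2383 windows of 1 Mb, limma called 0 above and 0 below 0, with a smallest Benjamini-Hochberg adjusted p of 0.053. At an unadjusted p under 0.05 there were 310 windows above and 354 below 0. In 858 windows (36.0%) all 4 tumours had the same sign, where independent signs would give 12.5%. The ratios of single autosomal probes also went together between arrays, with Pearson's r across probes from 0.64 to 0.81. Probes are not independent replicates. Without a dye swap such shared differences may hold the probes' own dye effects as well as copy number, and these cannot be told apart here. Centring on the mode gave 15 windows above and 226 below 0, window means gave 16 and 112, and leaving out tumour 4 gave 37 and 74.

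Whole autosomes other than chromosome 14 in tumour 4 differed little. Their medians lay between -0.07, for chromosome 9 in tumour 2, and 0.11, for chromosome 11 in tumour 1. Chromosomes 5, 11, 12, 15 and 19 were above 0 in 4 of 4 tumours and chromosome 13 was below 0 in 4 of 4, which is 6 of 19 chromosomes. The exact sign-flip p was 0.125 for each of them, the smallest possible. Centring on the mode turned this to 0 chromosomes above and 15 below 0 in all tumours. The chromosomes that carry Myc (15), Ctnnb1 (9), Cdkn2a (4), and Apc with Smad4 (18), all common targets in colorectal cancer, had medians between -0.07 and 0.05 in every tumour, which does not bear on changes of the genes themselves.

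The X and Y ratios of tumours 1 and 2 differed from those of tumours 3 and 4, and both the tumour and the control DNA differed in Y signal. Chromosome Y was at -2.05 (SE 0.11) in tumour 1 and -1.57 (SE 0.095) in tumour 2, and at 2.46 (SE 0.19) and 2.73 (SE 0.20) in tumours 3 and 4. Chromosome X was at 0.12, 0.79, -0.93 and -0.86 in tumours 1 to 4, with standard errors of at most 0.0062. The X value of tumour 1 lay between 0.08 and 0.37 under other settings. Y spots well above background made up 94.0% and 94.0% of the control channel for tumours 1 and 2 and 29.1% and 33.6% for tumours 3 and 4. In the tumour channel they made up 43.6%, 23.1%, 76.9% and 85.1%. The sex of the mice and the liver used on each array are not given in the sources used here. Sizes of the Y ratios are limited by background, and under normexp background correction they lay between -0.79 and 0.78 with the same signs.

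**Figure D3:**
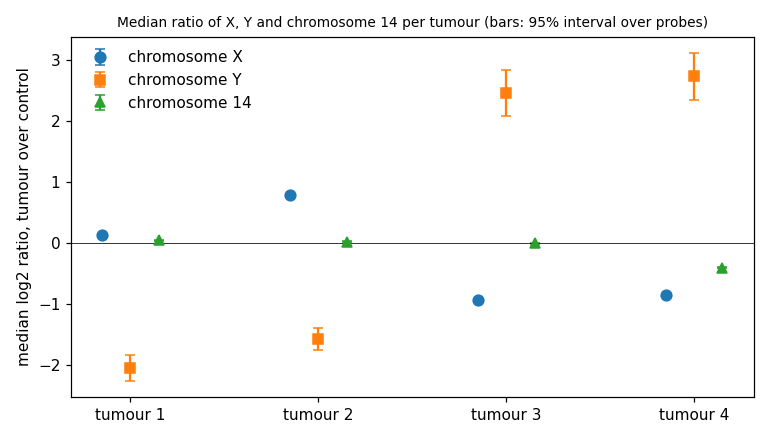
Median log2 ratio of tumour over control for chromosomes X, Y and 14 in each of the 4 tumours. Bars are 95% intervals over probes and are smaller than the symbols for X and 14. Tumour 1 has Y at -2.05 with X at 0.12, while tumour 2 has Y at -1.57 with X at 0.79.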

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

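Among 50 sets of 4 tumour values tested, 6 held a tumour far from the other 3 by Dixon's criterion, and chance flags about 1 set in 20. Many of the sets are segment means chosen because 1 tumour was called there, so flags among them carry little weight of their own. The chromosome 14 median of tumour 4 was -0.4057, with a gap of 0.89 of the range, and the segment over the same chromosome had a mean of -0.4248. On chromosome 2, tumour 4 stood apart with -0.6087 from 79788295 to 98049612, 0.4977 from 143643187 to 151038158 and 0.3532 from 101717192 to 143633329. Tumour 2 stood apart on chromosome 18 from 60925998 to 61740328, at -0.4329. No explanation was tested for these 6 values.

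The tests of the following patterns were chosen after the results were seen, except that of partial loss of Y and both tests of the chromosome 6 region, for which the bounds were written before their values were known. Each pattern was itself found in these data.

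Tumour 1 had low Y signal with X at 0.12 against control DNA that carries Y, while tumour 2 had low Y signal with X at 0.79. Tumour DNA with a full second X in all cells is argued against, because the X median of tumour 1 was lower than that of tumour 2 by a difference of -0.6658. Male tumour DNA with its Y kept is argued against by the Y median of -2.0463 (SE 0.11). Loss of Y in a part of the cells of a male tumour stays open: the tumour channel's Y signal was 1.1926 above the median of 3 channels with little Y signal. That value met the bound of 0.5 written in advance as a sign of this cause. The test was nevertheless judged void afterwards, because the 3 channels mix both dyes and range from -0.0264 to 1.5225, above the value itself. A single X without Y in all cells stays open too, with values on both sides. In tumour 1, 16 of 17 X windows of 10 Mb lay above 0, where 1 X in both DNAs would give 0. Only 1 of 246 autosomal windows without calls reached its X median. The end of X set tumour 1 apart, at -0.74 against -0.15, -0.03 and 0.03 in tumours 2 to 4. It was not tested by itself, but its probes are part of the X medians and of the last X window. In tumour 1 that window was the lowest, at -0.349, and the only X window not above 0.

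The 11 short gains of tumour 3 lay in regions of high probe density, at a median percentile of 96.0 of random regions with as many probes, which a regional wave of the array signal would give. The mean of the other 3 tumours was above 0 in 11 of 11, but 2 of these overlap the gain of tumour 1 and 1 was only 0.0043. In the 2 that overlap, tumours 2 and 4 were above 0 as well, at 0.12 and 0.18 in the first and 0.03 and 0.08 in the second. Spearman's rho of ratio with density across windows outside calls was 0.24, -0.02 and 0.08 in tumours 1, 2 and 4 against 0.49 in tumour 3. Loess on density brought that rho to 0.03 and the means to 0.16 to 0.38 against 0.22 to 0.45 before, so the average trend accounted for a part of them. After it 11 of 11 means kept a 95% interval over probes above 0. That cannot decide whether density is the whole cause. The gains were picked as high in these same values, and the intervals leave out scatter between regions. After the loess 4 of the 11 were still called, 3 means had fallen below 0.2, and why the other calls ended was not tested. Copy gains of tumour 3 alone cannot be told apart from a wave that is stronger on its array, whether or not it follows density. Of the 11 gains, 9 were still called after the other tumours were subtracted, which removes only what the arrays share equally.

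The focal loss on chromosome 6 in tumours 3 and 4 goes with a difference in the control DNA. In tumours 1 and 2 both channels had a mean signal over the region -2.3011 log2 from that of the control channel of tumours 3 and 4, with single values from -2.6505 to -1.8083. This is consistent with a region present in the control DNA of tumours 3 and 4 and absent, or nearly so, from the other DNA samples, such as a germline difference between littermates. Dim probes alone are argued against, because 85.7% of the control spots there were well above background. Deletion in the tumours themselves stays open, since no normal DNA of the same mice was analysed here.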

How the results depend on the processing

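Of 226 recomputed summary values, 151 stayed within 1.5 times the reported count, within its spread or on the same side of the threshold, and no X or Y median changed sign. All 188 recomputed segment means kept their sign. The segments were picked for means at least 0.2 from 0 in the same probes, so this was largely set in advance and does not cover their size. The chromosome 1 loss of tumour 3 came to -0.04 after each probe's median over the tumours was subtracted. The chromosome 6 loss of tumour 4 came to -0.06 with only spots well above background. Of the 27 calls, 9 were found in all 7 other value sets, 8 in 6 of 7 and 3 in under 4. The series value table equals the starting values, so that alternative moved nothing. Subtracting the other tumours and loess on probe density were chosen after seeing the data. Planned results for the Trp53 locus, genes, gene lists and antigen receptor loci, with their alternatives, and loess on GC content were not run, as positions and gene table differ in build. Filtering dim spots left no value for the chromosome 6 region from 41066997 to 41112757 in tumour 3. No paired analysis was possible because there is a single group. Leaving out a tumour does not alter the segments or sex chromosomes of the others. Signal over background limits the Y ratios and the chromosome 6 region, and probe noise (0.47 and 0.42) limits short gains in tumours 1 and 4. Except where stated, the cause was not tested.

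Without 1 tumour, the length shared by at least 2 ranged from 0.08 Mb to 34.8 Mb, autosomes of the same sign in all tumours from 6 to 9, autosomes at least 0.2 from 0 from 0 to 1 (0 without tumour 4), windows above 0 from 0 to 37 and windows below 0 from 0 to 74.

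Centring on the mode gave 16.1 Mb of calls in tumour 3, a shared length of 1.69 Mb (permutation p = 0.38), 15 autosomes of the same sign, 15 windows above and 226 below 0, and X medians of 0.0761, 0.7619 and -0.9012 in tumours 1, 2 and 4. These follow from its shift of each array by 0.02 to 0.05. Loess on mean signal gave 4 calls in tumour 1, 8 in tumour 2, 1.67 Mb shared by 3 tumours, X medians of 0.3724, 0.8977, -0.8585 and -0.7576 in tumours 1 to 4, and Y medians of -1.511, -1.2739 and 3.1169 in tumours 1, 2 and 4. Normexp background correction gave X medians of 0.0828, -0.8276 and -0.7923 in tumours 1, 3 and 4 and Y medians of -0.7871, -0.3474, 0.6376 and 0.7845 in tumours 1 to 4. With only spots well above background there were 5 calls in tumour 4, 7 windows above and 27 below 0, and Y medians of -1.4056, -0.5847, 1.186 and 1.5198.

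Each probe minus its median over the tumours gave 6 calls over 25.1 Mb in tumour 1, 21 over 15.9 Mb in tumour 2, 14.8 Mb in tumour 3, 40 calls in tumour 4 and a shared length of 0.24 Mb (permutation p = 0.67). Each probe minus the median of the other tumours gave 6 calls in tumour 1, 23 over 76.8 Mb in tumour 2, 37 over 58.0 Mb in tumour 3, 28 in tumour 4 and a shared length of 1.02 Mb (permutation p = 0.91). By construction, both can put a part of the mirror image of a change in 1 tumour into others. That part is limited because a median is subtracted, and whether it explains the added calls was not tested. Loess on probe density gave 9 calls over 14.8 Mb in tumour 3.

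Penalty 2 ln(n) gave 5, 10 and 41 calls in tumours 1, 2 and 3, and 43.8 Mb in tumour 3. Penalty 8 ln(n) gave 1 call of 4.86 Mb in tumour 2, 3 over 3.30 Mb in tumour 3 and 5 calls in tumour 4. At least 3 probes per segment gave 5 calls in tumour 2. Calls at 0.1 gave 69.1 Mb in tumour 2, 42 calls over 375.9 Mb in tumour 3 and a shared length of 34.78 Mb (permutation p = 0.46). Calls at 0.3 gave 1 call of 24.1 Mb in tumour 1, 7 over 6.83 Mb in tumour 3 and a shared length of 0.08 Mb (permutation p = 0.38). Over all alternatives the p of the shared length ranged from 0.0080 to 0.91. The mean of the chromosome probes gave 10 autosomes of the same sign, and the window mean gave 16 windows above and 112 below 0.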

Other observations

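The end of chromosome X differed from the rest of it in all 4 tumours, with the same border in each. It lay within 0.2 of 0 in tumours 2 to 4, where the rest of X was far from 0, and was far below 0 only in tumour 1. As tumour and control DNA differed in Y signal, the border is not shown to be a change in the tumours. In tumours 2 to 4 the end of X stayed near 0 with Y medians of -1.57, 2.46 and 2.73, on both sides of 0. In tumour 1, with a Y median of -2.05, it did not, and the cause of its low value was not tested. From 163660645 to 166421899, 247 probes had means of -0.74 (SE 0.030), -0.15 (SE 0.025), -0.03 (SE 0.020) and 0.03 (SE 0.027) in tumours 1 to 4. Before that border the mean was 0.11 in tumour 1, 0.78 in tumour 2 and -0.89 in tumour 4, and segments of tumour 3 had means between -1.06 and -0.68.

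Chromosome 9 in tumour 2 had the lowest autosomal median outside chromosome 14 in tumour 4, at -0.07, where the other tumours lay between -0.01 and 0.01. The shift lay in the distal part, where 4461 probes from 62772792 to 124061581 had a mean of -0.14 (SE 0.0058), against -0.03 (SE 0.0059) before it. It stayed under the call threshold of 0.2 and is called at 0.1.

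The region of chromosome 12 gained in tumour 4, from 114817826 to 116291089, had means of 0.22, -0.12 and 0.16 in tumours 1 to 3. Mouse chromosomes 6 and 12 carry antigen receptor loci, and whether the short calls on them overlap these loci was not analysed here.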
